A study of Mus musculus with 16 samples.

How the data were processed

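RNA from 16 samples of cultured spermatogonial stem cells was hybridised by the authors to Affymetrix mouse expression arrays with a biotin label, per the labels' protocols. RNA had been taken up in Trizol and treated with DNase, and cDNA was primed with oligo(dT), per the labels' protocols. The deposited values are linear probe set intensity values from 1.66 to 71511, already summarised to 1 value per probe set and array by the authors. The submitters' processing notes name Partek 6.4, GCRMA, MAS5 and Affymetrix Expression Console 1.1, with no role or order. Which of GCRMA and MAS5 gave the intensities is not given in the sources used here, and neither are the normalization between arrays, any filters or the siRNA sequences. Differences of probe sets near the lowest intensities are compressed by the floor of the signal.

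Of 45037 probe sets other than controls, 34945 were paired with 1 gene in the platform annotation, 932 with several and 9160 with none in the table used here. Only those with 1 gene were named, and 2 symbols were updated through the RefSeq gene table of GRCm38.p6. That table lacked the gene identifiers of 204 probe sets, which kept the symbol of the annotation. No coordinates were used. Each of 18194 genes was represented by its probe set with the highest mean log2 intensity over all 16 arrays. A gene was tested if at least 4 arrays lay above their own median, which left 11145 genes. No pair of arrays held identical values, and all 16 arrays were kept.

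Intensities were put on the log2 scale after adding 1, so that a log2 difference understates the change of dim genes. Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, in 1 fit of all 4 groups without covariates. Tests were two-sided with Benjamini-Hochberg adjustment over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05. Of all probe sets of the target genes, values came from a fit without the filter on dim genes. No label gives a batch or day. The comparisons, their tests, the other settings and 23 gene lists were fixed before the data were examined. Chosen after seeing the data were the fits without Bcl6b knockdown replicate 1 in comparisons that do not use it, a simulation with a lower spread, list tests between knockdowns without the targets of the 2 compared, and 6 tests of explanations.

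Named genes followed a fixed rule. It took the 3 targets, the 10 largest called rises and falls in each knockdown whose 4 arrays all lay beyond the 4 control arrays, and the 5 largest called differences in each direction between knockdowns. It also took up to 4 called members of each list, or the 2 with the smallest p where none was called, and the 10 largest changes shared by all knockdowns. Clone names were left out. Genes named beyond this rule, among them those called only without Bcl6b knockdown replicate 1, were chosen after their values were seen. Target values and per-array ranges of control probe sets are given beside these.

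The lists covered stem cell maintenance, growth factor response, spermatogonial differentiation, meiosis, other germ cell and developmental genes, the cell cycle, stress, interferon, metabolism and markers of somatic cell types. They were textbook groups, not chosen on these samples. Each list with at least 5 tested members was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A knockdown's own target was left out of its lists against control, and kept in the lists between knockdowns unless stated. With an estimated correlation and these lists, only the interferon list kept its call, in Pou3f1 knockdown against control and against both other knockdowns. Among lists that did not pass, some had a mean and a camera direction of opposite sign, such as macrophage markers in Etv5 knockdown (mean -0.15, camera upward).

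The pipeline was tested on simulated data with 200 of 11140 genes changed, in 10 draws per comparison. Of changes of 0.5 on the log2 scale 73.5% were recovered for Etv5 knockdown against control, 71.2% for Bcl6b knockdown and 70.6% for Pou3f1 knockdown, and of changes of 1 these were 97.2%, 96.8% and 96.8%. The shares of false calls were 4.80%, 4.81% and 3.97%. A shift of 0.3 in a list of 20 genes was found in 10 of 10 draws in each. An unshifted list passed in 1 of 10 draws for Etv5 against Bcl6b knockdown. The simulated noise was independent between genes and alike on all arrays. These shares therefore do not cover lists of correlated genes or a deviating array.

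Alternatives were median centring, quantile normalization, a pseudocount of 16, no filter or a filter at a mean log2 value of 5, the mean over probe sets, all probe sets, array weights, no intensity trend, only the groups compared, the replicate number as a factor, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.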

Results

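Gene expression was measured in cultures of mouse spermatogonial stem cells, the self-renewing germ cells of the testis. RNA was taken after 30 h of treatment with short interfering RNA (siRNA). The cultures had been started from Thy1-positive germ cells of C57BL/6 mice and were kept with GDNF at 20 ng/ml, its soluble co-receptor GFRA1 at 150 ng/ml and FGF2 at 1 ng/ml. The 16 arrays formed 4 groups of 4: a negative control siRNA and knockdowns of Etv5, Bcl6b and Pou3f1, which encode transcription factors. Median intensity over all probe sets was between 15.6 and 17.1 on every array, and 11145 genes were bright enough to be tested. The number of arrays limits the precision. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which can be technical.

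Each siRNA lowered its own target. Etv5 intensity was 1099 ± 385 (SD, n = 4) in Etv5 knockdown and 2969 ± 84.0 in control (n = 4), a log2 difference of -1.49 ± 0.21 (SE) with an adjusted p of 0.00115. Bcl6b intensity was 721 ± 79.4 in Bcl6b knockdown and 1453 ± 83.1 in control, a log2 difference of -1.01 and an adjusted p of 1.67e-04. Pou3f1 intensity was 415 ± 71.7 in Pou3f1 knockdown and 661 ± 21.8 in control, a log2 difference of -0.68 and an adjusted p of 0.00103. Bcl6b also fell in Etv5 knockdown, to 686 ± 142, with a log2 difference of -1.10 and an adjusted p of 6.21e-05. Etv5 did not pass the test in Bcl6b knockdown (log2 difference -0.10, adjusted p 0.813, and 0.15 without Bcl6b knockdown replicate 1) or in Pou3f1 knockdown (0.05, adjusted p 0.98). Pou3f1 did not pass it in Etv5 knockdown (-0.11, adjusted p 0.8) or in Bcl6b knockdown (-0.08, adjusted p 0.656), nor Bcl6b in Pou3f1 knockdown (0.13, adjusted p 0.762).

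Dimmer probe sets of Etv5 differed by -1.69 and -1.68 in Etv5 knockdown, with adjusted p of 0.393 and 0.752 in a fit of all probe sets. A dimmer Pou3f1 probe set differed by -0.84 in Pou3f1 knockdown, with an adjusted p of 0.208. These 3 differences passed the test without Bcl6b knockdown replicate 1, at adjusted p of 3.31e-04, 1.37e-04 and 0.0024.

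**Figure D1:**
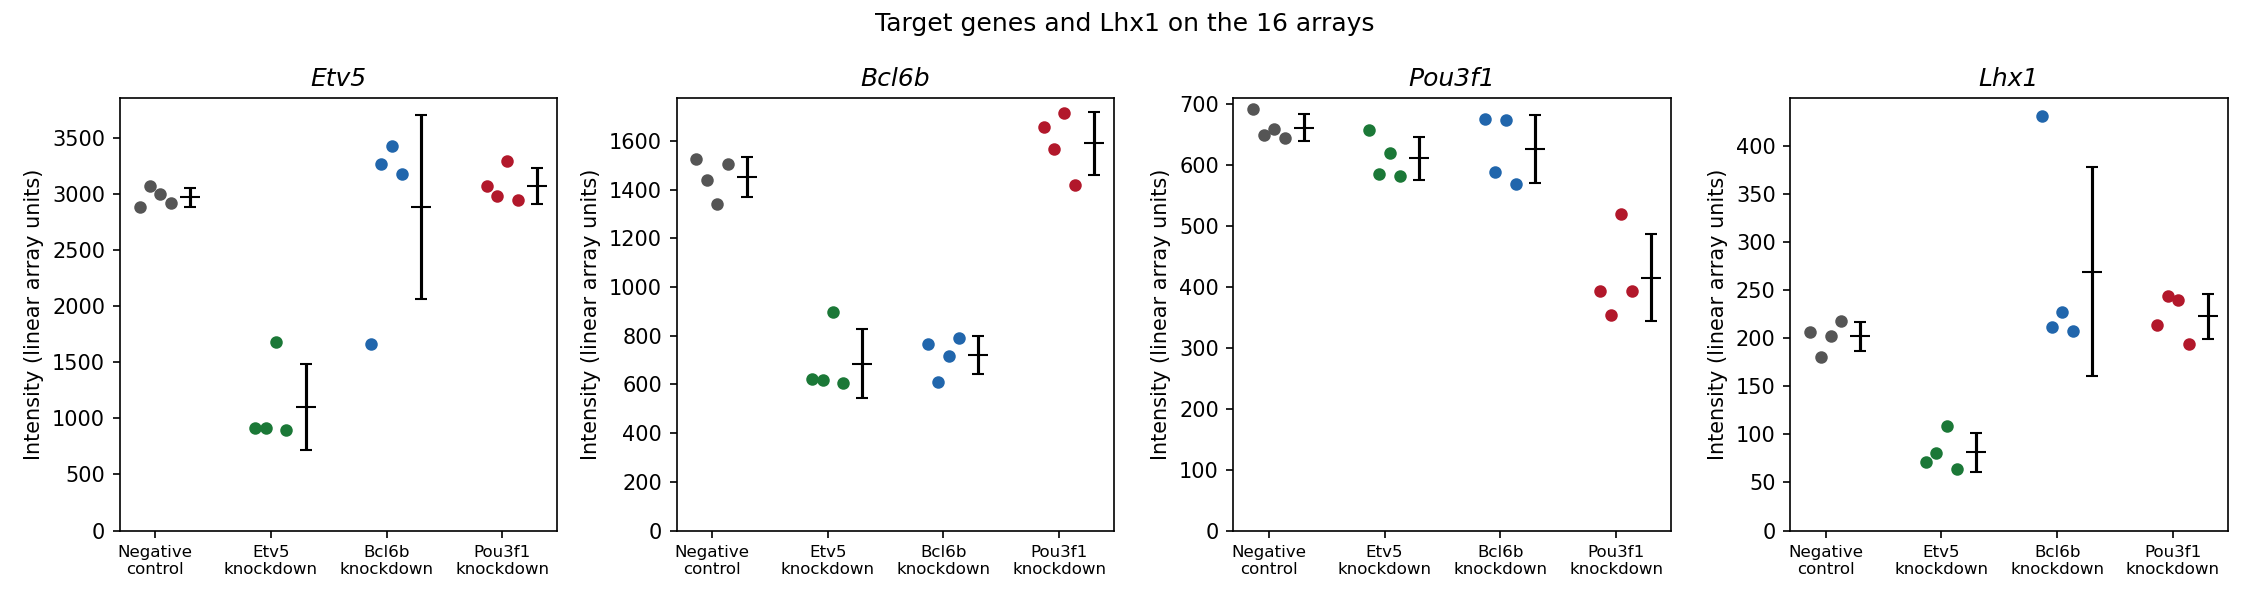
Intensity in linear array units of the brightest probe set of Etv5, Bcl6b, Pou3f1 and Lhx1 on each of the 16 arrays (points), with the mean and SD of each group of 4 (black). Etv5 averaged 1099 in its knockdown and 2969 in control, Bcl6b averaged 686 in Etv5 knockdown and 721 in its own, and Pou3f1 averaged 415 in its knockdown.

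Bcl6b knockdown replicate 1 stood apart from the other 15 arrays. Its mean correlation with the other arrays was 0.964, against 0.993 to 0.995 elsewhere. The log2 signal of the 3' minus the 5' control probe set was 1.03 for Gapdh and 3.08 for Actb there, against -0.53 to -0.45 and 0.62 to 0.76 on the other arrays. Etv5 read 1660 on that array and 3175 to 3424 on the other Bcl6b knockdown arrays. The median residual SD over genes was 0.133 with this array and 0.0852 without it. All counts were therefore also made without it, a step chosen after seeing the data, and every gene called with 16 arrays was also called in that fit.

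**Figure D2:**
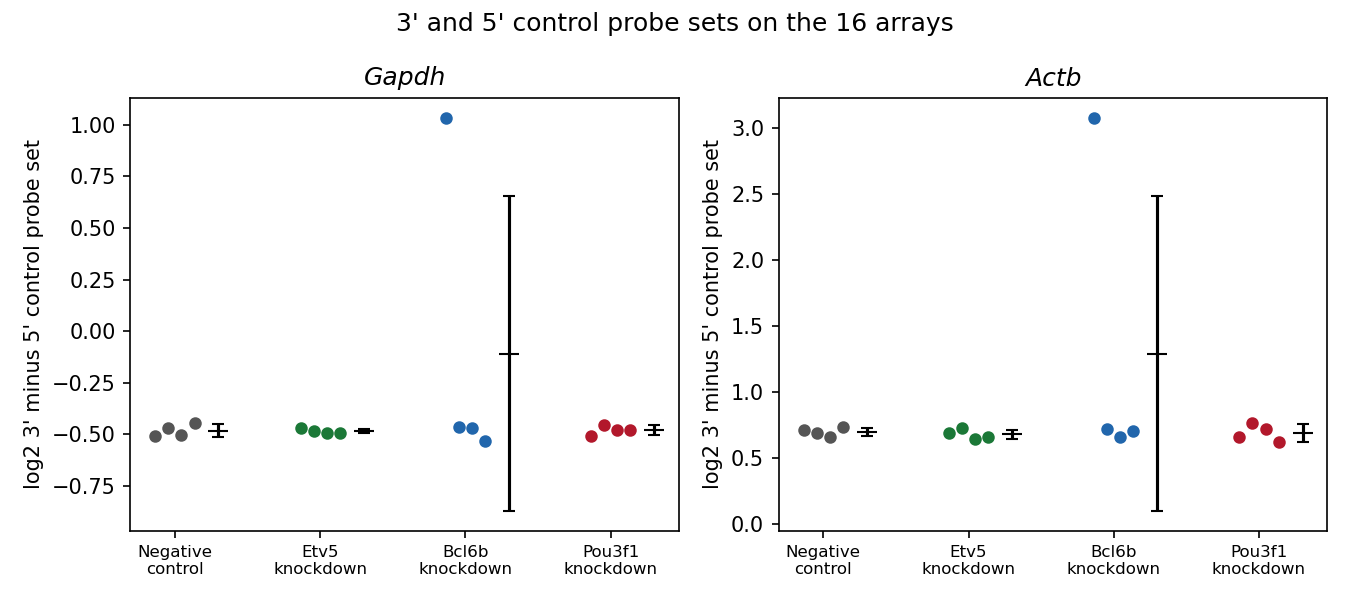
Log2 signal of the 3' minus the 5' control probe set of Gapdh and Actb on each of the 16 arrays (points), with the mean and SD of each group of 4 (black). Bcl6b knockdown replicate 1 lies at 1.03 and 3.08, above all other arrays.

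The comparison of Etv5 knockdown with control asked which genes depend on this transcription factor. Among regulators of stem cell maintenance and genes that respond to GDNF, 5 fell besides Etv5. The log2 difference was -1.33 ± 0.20 for Lhx1 (SE, n = 4 per group; adjusted p 0.00193), -1.10 for Bcl6b, -0.82 for the chemokine receptor gene Cxcr4, -0.56 for Nefm and -0.37 for Egr2. Other large falls were those of Mrc1 (-1.31), Plvap (-1.30), Tnfrsf25 (-1.15), Crmp1 (-1.12), Ramp2 (-1.09), Sema7a (-1.04) and Mfsd4a (-1.01). The largest rises were those of Ankrd29 (1.31), Camk2n1 (1.23), the keratin gene Krt18 (1.16), Ighm (1.15), Exoc4 (1.11) and Phex (1.04), followed by Tcfl5, Cacna1h, Rasgrf1 and Mycl at 0.82 to 0.89. Of these, Ankrd29, Camk2n1, Exoc4, Phex and Tcfl5 rose in all 3 knockdowns. Such shared rises cannot be told apart from an effect of the control siRNA. Rasgrf1 and Mycl lay below the median of every array in control, near the floor of the signal, so the size of their rise is uncertain. Sohlh1, a transcription factor of differentiating spermatogonia, rose by 0.61 with an adjusted p of 0.00116. By the naming rule, all 4 knockdown arrays lay beyond all 4 control arrays in each gene named for a large rise or fall.

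Of the 22 tested maintenance regulators other than Etv5, 3 fell, and 4 did so adjusted over the list alone. Leaving out Bcl6b knockdown replicate 1, 8 fell and 1 rose. The list as a whole was lower in limma's camera test, with an adjusted p of 0.00158 (adjusted p = 0.211 with an estimated correlation). Of 14 GDNF-responsive genes 5 fell, and 7 adjusted over the list alone, with an adjusted p of 4.52e-05 (adjusted p = 0.128 with an estimated correlation). Without that array 7 fell. Bcl6b, Lhx1 and Cxcr4 belong to both lists. Of 19 FGF and MAPK feedback genes the cyclin gene Ccnd1 fell (-0.34), also adjusted over the list alone, and 5 fell without that array. The list was lower at an adjusted p of 1e-03 (adjusted p = 0.128 with an estimated correlation). Of 16 spermatogonial differentiation genes Sohlh1 rose, with 2 adjusted over the list alone and 4 without that array. The list was higher at an adjusted p of 1e-03 (adjusted p = 0.129 with an estimated correlation).

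Glycolysis and hypoxia genes were higher as a list in Etv5 knockdown (adjusted p 4.52e-05; adjusted p = 0.108 with an estimated correlation), with 1 of 17 called, the mitochondrial protein gene Bnip3 at 0.49. With adjustment over the list alone 2 rose and 1 fell, and without Bcl6b knockdown replicate 1, 7 rose and 1 fell. Fibroblast and feeder markers were higher (adjusted p 0.0142; adjusted p = 0.129 with an estimated correlation), with Vim of 23 called, at 0.33, also adjusted over the list alone, and 5 without that array. Germ cell identity and piRNA genes were higher (adjusted p 0.0348; adjusted p = 0.129 with an estimated correlation), interferon response genes were higher (adjusted p 4.52e-05; adjusted p = 0.298 with an estimated correlation) and G2 and M phase genes were lower (adjusted p 0.0306; adjusted p = 0.534 with an estimated correlation). No member of these 3 lists was called, over all genes or adjusted over the list alone, and without that array 1 germ cell identity and 1 interferon gene rose. The interferon list mean was 0.0125 to 0.267 on the Etv5 knockdown arrays and -0.134 to 0.183 on the control arrays, so the groups overlapped. The G2 and M phase list lost its call without Etv5 knockdown replicate 1 or 4 or control replicate 3 (camera adjusted p 0.0704, 0.254 and 0.0745). Germ cell identity genes lost theirs without Etv5 knockdown replicate 3 (0.0804) or control replicate 4 (0.112). Of 20 p53 and apoptosis genes Bcl2 rose by 0.60, and Zmat3 (-0.32) and Ei24 (-0.21) fell. When adjusted over the list alone 2 rose and 5 fell, and without Bcl6b knockdown replicate 1, 2 rose and 6 fell. The list did not pass (adjusted p 0.0592, and 0.0277 without Bcl6b knockdown replicate 1, where adjusted p = 0.142 with an estimated correlation). Of 7 neural genes Sox3 rose by 0.74 and Egr2 fell, with 1 higher and 2 lower adjusted over the list alone, and the list did not pass (adjusted p 0.963). No meiosis gene of 21, pluripotency gene of 11, S phase gene of 21, cholesterol synthesis gene of 18 or unfolded protein gene of 20 passed, over all genes or adjusted over the list alone. In the fit without that array 2 meiosis genes and 1 pluripotency gene rose, and 2 S phase and 2 unfolded protein genes fell. The adjusted p of these lists were 0.0766, 0.0569, 0.205, 0.963 and 0.805.

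In all, 233 genes were called in Etv5 knockdown, 146 higher and 87 lower, of which 16 differed at least 2-fold. Without Bcl6b knockdown replicate 1 there were 1061, with 510 higher and 551 lower, and without control replicate 3 there were 128. All 8 arrays separated the groups in 17.3% of tested genes, where chance gives 2.86%. Of the 87 lower genes 18 also fell in Bcl6b knockdown and 12 in Pou3f1 knockdown; 24 differed from both other knockdowns when tested directly. Of the 146 higher genes 95 also rose in Bcl6b knockdown and 75 in Pou3f1 knockdown, and 7 differed from both in direct tests.

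The comparison of Bcl6b knockdown with control asked which genes depend on Bcl6b. The TWEAK receptor gene Tnfrsf12a fell, with a log2 difference of -1.05 ± 0.14 (SE, n = 4 per group; adjusted p 4.83e-04), as did the actin regulator Cfl2 (-0.80), Abat (-0.77), Gamt (-0.75), Sspn (-0.72), Slc35f6 and Necap1 (-0.69), Ank2 (-0.68) and Impact (-0.67). Ccnd1 (-0.59) and Fosl1 (-0.55) also fell. Of these, Sspn and Ccnd1 fell in all 3 knockdowns. Clone names aside, the largest rises with all 4 arrays above control were those of Sgip1 (1.24), Phex (1.20), Exoc4 (1.18), the chemokine gene Ccl5 (1.07), Mid1 and Ppargc1a (0.99), Insyn2a (0.95), Cfp (0.93), Mmp13 (0.91) and Ankrd29 (0.88). Among these, Phex, Exoc4 and Ankrd29 rose in all 3 knockdowns. Sgip1 averaged only 11.1 in control, below the median of every array, so the size of its rise is uncertain. The GDNF receptor gene Ret rose by 0.35 with an adjusted p of 0.00509, but its mean over all probe sets differed by -0.0590.

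Of 27 tested interferon response genes 6 rose in Bcl6b knockdown, 15 did so adjusted over the list alone or without replicate 1, and none fell, with Ifih1 at 0.70, Oas1a at 0.69, Irf7 at 0.60 and Ifit2 at 0.52. The list was higher in the camera test, with an adjusted p of 5.15e-11 (adjusted p = 0.369 with an estimated correlation). Its mean was 0.16 to 0.50 on the Bcl6b knockdown arrays and -0.13 to 0.18 on the control arrays, so the groups overlapped. Glycolysis and hypoxia genes were higher (adjusted p 0.00334; adjusted p = 0.369 with an estimated correlation), with 1 of 17 called, Bnip3 at 0.41, and 4 adjusted over the list alone or without replicate 1. The mean of that list was 0.247 above control on Bcl6b knockdown replicate 1, and 0.0546 to 0.0846 on the other Bcl6b knockdown arrays. G2 and M phase genes were lower (adjusted p 0.0326; adjusted p = 0.803 with an estimated correlation) with no member called or passing adjusted over the list alone, and without replicate 1 the adjusted p was 0.492.

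The remaining lists did not pass in Bcl6b knockdown, with adjusted p between 0.345 and 0.865. Of 20 p53 and apoptosis genes 4 were called, Bcl2 (0.65) and Fas (0.25) higher and Eda2r (-0.62) and Ccng1 (-0.20) lower. With adjustment over the list alone 3 rose and 3 fell, and without replicate 1, 3 rose and 4 fell. Of the FGF and MAPK feedback genes 2 of 20 were called, Ccnd1 and Fosl1, both lower. When adjusted over the list alone 1 rose and 5 fell, and without replicate 1, 3 fell. Ret was the called maintenance regulator, Tcl1 (0.51) the called pluripotency gene and Vim (0.29) the called fibroblast marker, each also the only member adjusted over the list alone. No GDNF-responsive, differentiation, meiosis, germ cell identity, neural, S phase, cholesterol synthesis or unfolded protein gene passed, over all genes or adjusted over the list alone. The S phase list averaged -0.325 and the unfolded protein list 0.159 on replicate 1, against -0.0499 to -0.0179 and -0.131 to -0.0892 on the other Bcl6b knockdown arrays. The unfolded protein list was lower, with 6 members called and an adjusted p of 0.0258, without that replicate (adjusted p = 0.396 with an estimated correlation).

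In Bcl6b knockdown 358 genes were called, 184 higher and 174 lower, of which 7 differed at least 2-fold. Median centring gave 126 higher and 617 lower, and without replicate 1 there were 1220, with 454 higher and 766 lower. A fit of only the groups compared gave 62, and leaving out control replicate 2 gave 191. The groups were separated in 14.7% of tested genes.

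Interferon-stimulated genes fell in Pou3f1 knockdown. Ccl5 differed from control by -1.97 ± 0.22 on the log2 scale (SE, n = 4 per group; adjusted p 1.23e-04), and the antiviral gene Rsad2 by -1.57. The chemokine gene Cxcl10 (-1.09), Oas1a (-1.08), Oasl1 (-1.01), Usp18 (-0.96), the double-stranded RNA receptor gene Tlr3 (-0.93), Ifit1 (-0.90), Mx2 (-0.88) and Iigp1 (-0.83) also fell. Of the 27 tested interferon response genes 20 fell, 24 did so adjusted over the list alone, 26 without Bcl6b knockdown replicate 1, and none rose. The median difference was -0.60 and the camera adjusted p was 6.79e-36 (adjusted p = 0.0228 with an estimated correlation, and 0.204 without Bcl6b knockdown replicate 1). The list means of the 4 Pou3f1 knockdown arrays were -0.83 to -0.49, and those of the control arrays -0.13 to 0.18.

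**Figure D3:**
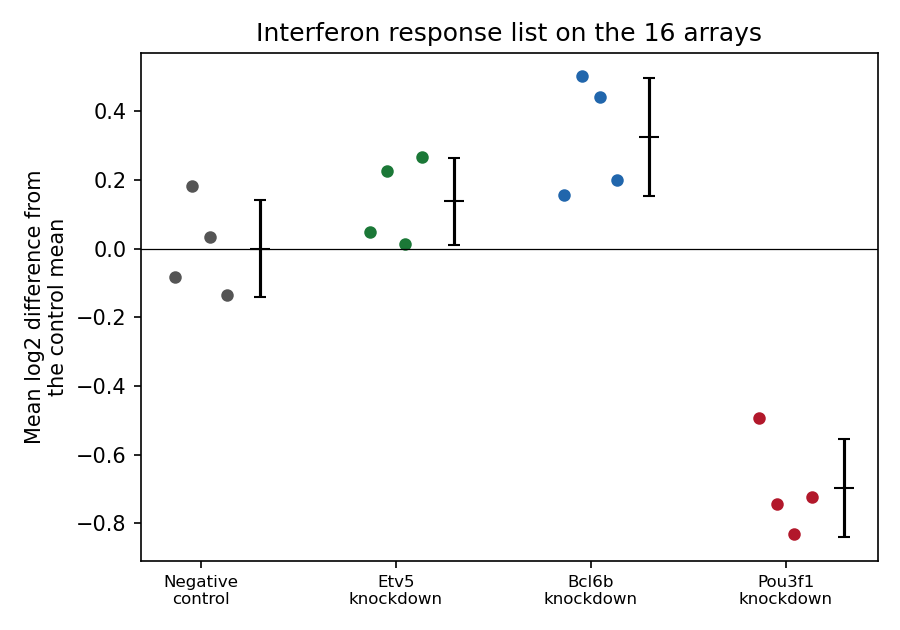
Mean log2 difference of the 27 interferon response genes from the control mean on each of the 16 arrays (points), with the mean and SD of each group of 4 (black). Pou3f1 knockdown arrays lie at -0.83 to -0.49, below all others, and Bcl6b knockdown arrays at 0.16 to 0.50.

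The largest rises in Pou3f1 knockdown were those of Ankrd29 (1.39), Exoc4 (1.17), Phex (1.06), Tcfl5 (0.90), Pkia (0.88), Crls1 (0.81), Ube2q2 (0.76), Camk2n1 (0.75), Chmp3 (0.72) and Col11a1 (0.71). All of these except Pkia and Col11a1 rose in all 3 knockdowns. Ret rose by 0.38, Tcl1 by 0.56, Pdk1 by 0.38, Bnip3 by 0.30 and Vim by 0.35, and Ccnd1 fell (-0.35). Of 20 p53 and apoptosis genes 2 rose and 4 fell, with Bcl2 at 0.51, Ccng1 at -0.42, Zmat3 at -0.26 and Trp53inp1 at -0.21. With adjustment over the list alone 2 rose and 7 fell. Adjusted over the list alone 1 maintenance regulator, 2 FGF and MAPK feedback genes, 1 pluripotency gene, 2 glycolysis genes and 3 fibroblast markers (1 higher, 2 lower) passed, and no GDNF-responsive, differentiation, meiosis, germ cell identity, neural, S phase, G2 and M phase, cholesterol synthesis or unfolded protein gene did. No list other than the interferon list passed the camera test, with adjusted p between 0.0508 and 0.908. Without Bcl6b knockdown replicate 1, 4 FGF and MAPK feedback genes fell, 4 glycolysis genes rose, and of p53 and apoptosis genes 2 rose and 7 fell. In that fit, maintenance regulators and the meiosis, neural and glycolysis lists were higher at an adjusted p of 0.0400, and cholesterol synthesis at 0.0199. None of these passed with an estimated correlation (adjusted p = 0.23 with an estimated correlation for the neural list and 0.555 for the others). In this comparison 251 genes were called, 115 higher and 136 lower, and 8 differed at least 2-fold. Without that array there were 1268, with 479 higher and 789 lower, and without control replicate 3 there were 129. The groups were separated in 18.1% of tested genes.

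**Figure D4:**
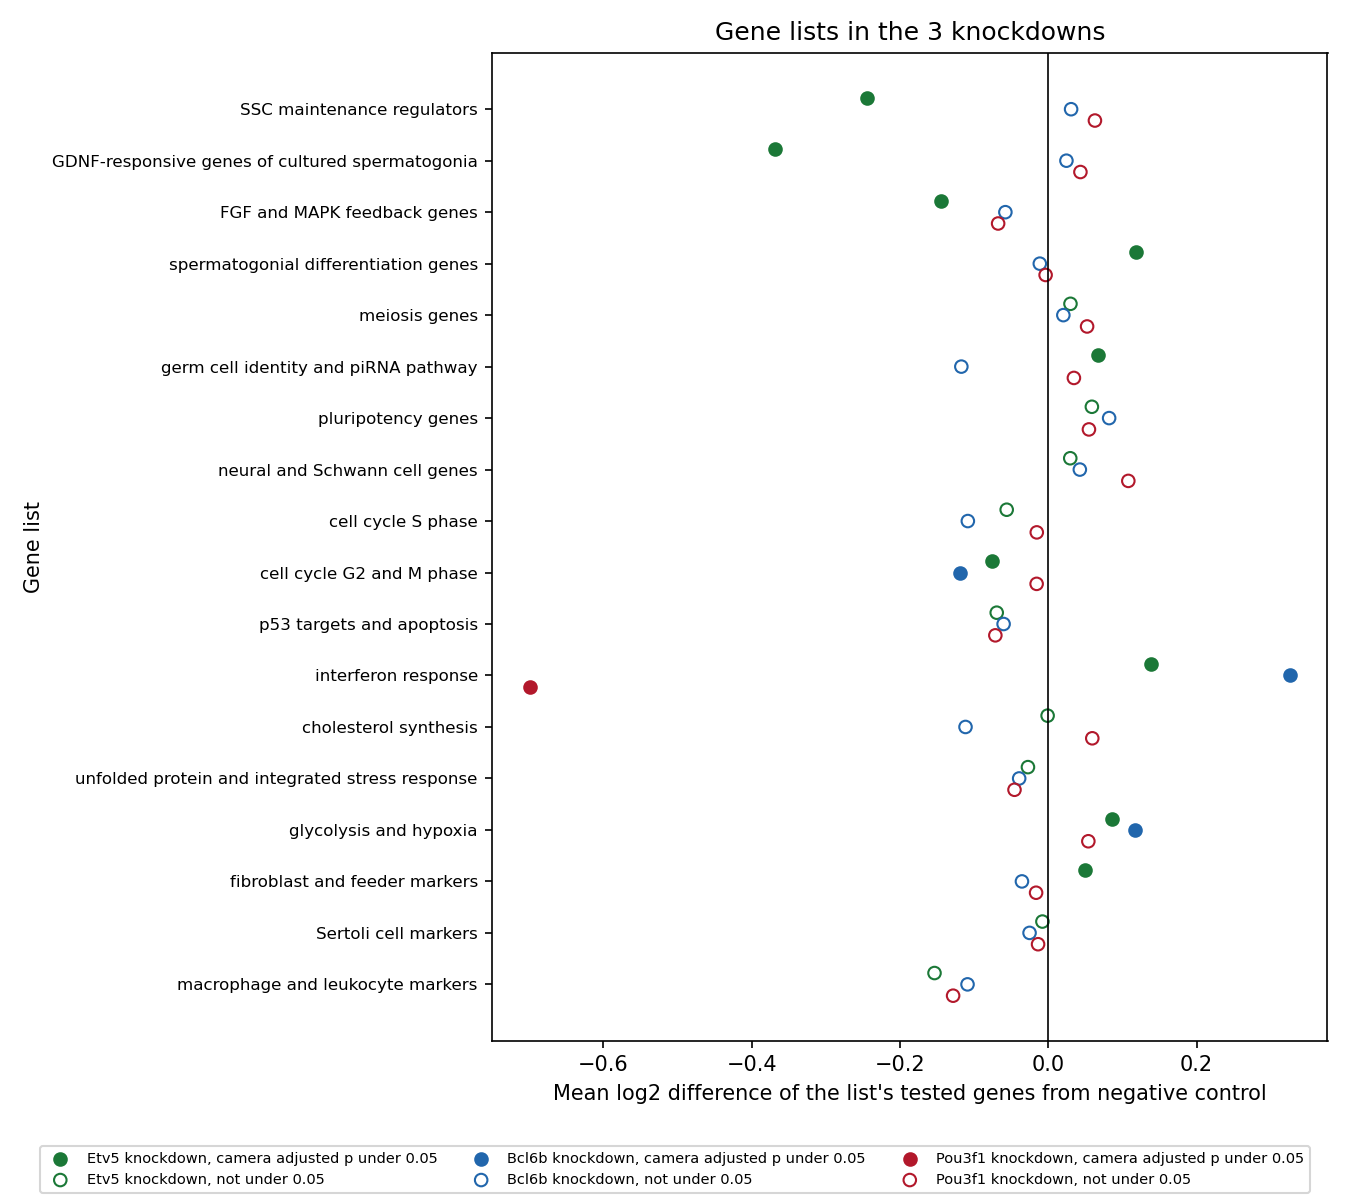
Mean log2 difference from negative control of the tested genes of 18 gene lists in each knockdown. Filled points had a camera adjusted p under 0.05 at the preset correlation. With an estimated correlation only the interferon list in Pou3f1 knockdown kept its call, and it lost it without Bcl6b knockdown replicate 1. The interferon response list lies at -0.70 in Pou3f1 knockdown and 0.33 in Bcl6b knockdown, and the GDNF-responsive list at -0.37 in Etv5 knockdown.

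Among markers of other cell types, Vim rose in all 3 knockdowns, and other fibroblast markers were called only without Bcl6b knockdown replicate 1. In control the median level of the 23 fibroblast and feeder markers lay at percentile 95.71 of all tested genes, the highest of all lists. For the 19 germ cell identity genes it lay at percentile 68.48. In which cells of the cultures a change arose was not tested. No member of the lists of Sertoli cell markers (5 tested) or macrophage and leukocyte markers (9 tested) was called in any comparison with all 16 arrays. The macrophage and leukocyte markers were dim, with a median level at percentile 12.43 in control. The lists of cell type markers did not hold Mrc1, Plvap or Ramp2, which fell in Etv5 knockdown. They therefore cannot exclude a change in other cells. Adjusted over the list alone 1 macrophage marker was lower in Etv5 knockdown than in control, and 1 was higher in Etv5 than in Bcl6b knockdown. Between Bcl6b and Pou3f1 knockdown 1 Sertoli marker passed in this way. Without Bcl6b knockdown replicate 1, the Sertoli marker Clu rose by 0.15 in Etv5 and in Pou3f1 knockdown, Rhox5 fell (-0.15) in Etv5 knockdown, and 1 macrophage marker was higher in Etv5 than in Bcl6b knockdown. Camera adjusted p values for these lists against control lay between 0.851 and 0.971. The lysozyme gene Lyz2 differed by -1.57 in Etv5 knockdown with an adjusted p of 0.0747, and 0.00893 without Bcl6b knockdown replicate 1. Lists with too few tested members for the camera test were those of spermatids (3), mesoderm (3), Leydig cells (4), peritubular myoid cells (4) and endothelium (1). With all 16 arrays, among these only Lhx1, a mesoderm gene, was called, in Etv5 knockdown against each other group. Adjusted over the list alone 2 mesoderm genes passed in Etv5 knockdown, against each other group, and 1 Leydig gene and the endothelial gene in Bcl6b knockdown against control.

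Knockdowns were also compared with each other, in the same fit of all 4 groups, so the control arrays added to the estimate of the spread. Lhx1 was lower in Etv5 than in Bcl6b knockdown by -1.68 ± 0.20 (SE, n = 4 per group; adjusted p 0.00119), as were Plvap (-1.52), Mrc1 (-1.35), Ramp2 (-1.34), Cxcr4 (-1.04), Shisa6 (-0.92), Spry4 (-0.61), Egr2 (-0.53) and Ret (-0.36). Ret was not called in Etv5 knockdown against control. It rose in Bcl6b knockdown, where its mean over probe sets had the opposite sign. Shisa6 was dim, at 12.6 in Etv5 and 25.6 in Bcl6b knockdown. Ighm (1.15), Krt18 (1.07), Tnfrsf12a (1.03), Cacna1h (0.96) and Slc4a4 (0.95) were higher. Lhx1 read 431 on Bcl6b knockdown replicate 1 and 207 to 228 on the others of that group, and its difference was -1.43 without that array. Maintenance regulators were lower in Etv5 knockdown, with 5 of 23 called, Etv5 among them, and 9 adjusted over the list alone (camera adjusted p 1.22e-04; adjusted p = 0.209 with an estimated correlation). GDNF-responsive genes were lower, with 6 of 15 called, Etv5 among them, and 2 higher and 7 lower adjusted over the list alone (1.46e-04; adjusted p = 0.209 with an estimated correlation). Without Etv5 and Bcl6b, 4 of 21 and 5 of 13 were lower. Adjusted over the list alone 8 maintenance regulators were lower, and 2 GDNF-responsive genes were higher and 6 lower. The lists were lower at 0.00101 and 0.0018 (adjusted p = 0.231 with an estimated correlation). Differentiation genes were higher (0.00553; adjusted p = 0.231 with an estimated correlation), with Sohlh1 alone called at 0.49 and 3 adjusted over the list alone. Germ cell identity genes (0.00448) and fibroblast markers (0.0155) were higher and interferon genes (1.22e-04) lower, with none called, 2 germ cell identity genes adjusted over the list alone, and adjusted p = 0.194, 0.209 and 0.502 with an estimated correlation. Of FGF and MAPK feedback genes 2 of 20 were higher and 2 lower, Etv5 among the latter, with 4 higher and 5 lower adjusted over the list alone. Of neural genes 1 of 7 was higher and 2 lower, with 2 and 2 adjusted over the list alone, and of p53 and apoptosis genes 1 of 20 was higher and 1 lower, with 1 and 3. These lists did not pass (adjusted p 0.183, 0.784 and 0.55). Without Bcl6b knockdown replicate 1 the FGF list, which held Etv5, was lower at 0.0173 (adjusted p = 0.337 with an estimated correlation), and the unfolded protein list higher at 0.0355 (adjusted p = 0.258 with an estimated correlation). Adjusted over the list alone 1 meiosis, 1 glycolysis and 1 macrophage gene passed. In this comparison 166 genes differed, 101 higher and 65 lower in Etv5 knockdown, against 212 and 47 with median centring and 502 in all without Bcl6b knockdown replicate 1. A fit of only the groups compared gave 2, and leaving out Etv5 knockdown replicate 1 gave 74.

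Against Pou3f1 knockdown, Etv5 knockdown had lower Etv5 (-1.53), Lhx1 (-1.47), Mrc1 (-1.32), Ramp2 (-1.27), Bcl6b (-1.23), Nefm (-0.64) and Ret (-0.39), and higher Ccl5 (2.01), Rsad2 (1.52), Oas1a (1.34), Cxcl10 (1.21), Krt18 (1.16) and Stra8 (0.37), a gene induced by retinoic acid. Against control, Ret rose in Pou3f1 knockdown and was not called in Etv5 knockdown. Of 27 interferon genes 21 were higher and 26 adjusted over the list alone, with a camera adjusted p of 1.43e-61 (adjusted p = 0.0024 with an estimated correlation). Maintenance regulators were lower, with 5 of 23 lower and 1 higher, and 10 lower and 1 higher adjusted over the list alone (1.04e-07; adjusted p = 0.0536 with an estimated correlation). GDNF-responsive genes were lower, with 5 of 15 lower and 1 higher, and 9 lower and 1 higher adjusted over the list alone (1.86e-07; adjusted p = 0.0536 with an estimated correlation). Of the targets, Etv5 was among the lower genes of both lists and Pou3f1 (0.57) was the higher one. Without these targets, 4 of 21 and 4 of 13 were lower, and 8 of each list were lower adjusted over the list alone. Both lists were then lower at a camera adjusted p of 2.57e-08, and at 0.0475 with an estimated correlation. That test was run with all 16 arrays only, so its dependence on Bcl6b knockdown replicate 1 was not tested. Differentiation genes were higher (0.00244; adjusted p = 0.177 with an estimated correlation), with 2 of 16 called and 3 adjusted over the list alone. Fibroblast markers were higher (8.73e-04; adjusted p = 0.0536 with an estimated correlation), with none called and 1 adjusted over the list alone. The glycolysis list was higher and the FGF and cholesterol lists lower, each at an adjusted p of 0.0404 (adjusted p = 0.22 with an estimated correlation), and G2 and M phase genes were lower at 0.0219 (adjusted p = 0.57 with an estimated correlation). Members called in these were Bnip3 (0.19) and Etv5, and adjusted over the list alone 2 glycolysis genes were higher, and of FGF and MAPK feedback genes 2 were higher and 4 lower. The FGF list depended on Etv5: without it the mean went from -0.144 to -0.0711, 1 gene passed adjusted over the list alone, and the list did not pass (adjusted p 0.169). Of neural genes Egr2 (-0.55) and Zic1 (-0.35) were lower, with 1 higher and 2 lower adjusted over the list alone, and Ccng1 was the p53 target called (0.25), with 1. These lists did not pass (adjusted p 0.0817 and 0.715). In all, 161 genes differed, 104 higher and 57 lower in Etv5 knockdown, 709 without Bcl6b knockdown replicate 1 and 85 without Etv5 knockdown replicate 4.

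Interferon-stimulated genes were higher in Bcl6b than in Pou3f1 knockdown. Ccl5 was higher in Bcl6b knockdown by 3.04 ± 0.22 (SE, n = 4 per group; adjusted p 2.14e-06), Rsad2 by 2.17, Oas1a by 1.76, Cmpk2 by 1.67, Mx1 by 1.64, Tlr3 by 1.1 and Ifit2 by 0.92. Of 27 interferon genes 24 were higher and 26 adjusted over the list alone (camera adjusted p 1.49e-46; adjusted p = 0.00809 with an estimated correlation). Bcl6b (-1.14), Slc4a4 and Cfl2 (-0.79), Aldh6a1 (-0.78) and Tnfrsf12a (-0.76) were lower. Cholesterol synthesis genes were lower at an adjusted p of 0.00661 (adjusted p = 0.2 with an estimated correlation) with no member called and 3 adjusted over the list alone. G2 and M phase genes were lower at 0.0186 (adjusted p = 0.775 with an estimated correlation), and at 0.256 without Bcl6b knockdown replicate 1, with no member called. Maintenance regulators and GDNF-responsive genes called were the targets Bcl6b and Pou3f1, with 2 of each list adjusted over the list alone. Ccnd1 (-0.24) was the called FGF and MAPK feedback gene, with 1 higher and 2 lower adjusted over the list alone, and of p53 and apoptosis genes Trp53inp1 (0.24) and Ccng1 (0.22) were higher and Eda2r (-0.41) lower, with 3 higher and 1 lower adjusted over the list alone. The mean over the probe sets of Ccng1 differed by -0.0565. The other lists did not pass, with adjusted p between 0.0848 and 0.968. In all, 243 genes differed, 161 higher and 82 lower in Bcl6b knockdown, against 116 and 215 with median centring and 570 in all without replicate 1. A fit of only the groups compared gave 74.

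Some genes changed the same way in all 3 knockdowns: 68 were higher and 7 lower than in control. Exoc4, Phex, Ankrd29, Tcfl5, Crls1, Camk2n1, Zfp667, Tk2 and Pik3ip1 rose by at least 0.60 in each, and the lamin gene Lmnb2 fell, with log2 differences of -0.64 to -0.60. Etv5 and Bcl6b knockdown shared 113 calls in the same direction and none in opposite directions, Etv5 and Pou3f1 knockdown 87 and 1, and Bcl6b and Pou3f1 knockdown 102 and 12. With 1 array left out, calls shared in the same direction ranged from 63 to 421, 56 to 466 and 57 to 496, highest without Bcl6b knockdown replicate 1. Independent lists of these sizes would share 3.77, 2.57 and 4.02 genes. Simulated unchanged knockdowns against shared control arrays shared at most 1, 0 and 0 genes in 100 draws. These draws held no knockdown effect, so few calls and low overlaps were likely beforehand. They cannot tell how many of the shared calls came from the shared control arrays. With the control arrays split between the comparisons, the shared counts averaged 39.2, 36.2 and 35.2. Each comparison then had fewer control arrays and so less power. The lower counts therefore do not measure the part played by shared controls. The correlations across genes of the differences from control were 0.404, 0.485 and 0.275, where shared controls alone gave 0.5, 0.499 and 0.499. The covariances were 0.0119, 0.0104 and 0.00803, against 0.00769 in each simulation, and against 0.00281 with the spread taken without Bcl6b knockdown replicate 1, a simulation added after seeing the data. Genes are not independent replicates.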

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

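Of the tests in this part, those of RNA degradation, of a wrong label, of a deviating control array, of leukocytes, of array scaling and of siRNA duplexes were chosen only after the result was seen. Samples that lay far from the other 3 of their group were looked for with Dixon's criterion, by which chance picks out about 1 in 20 groups. It picked out 8 of 24 groups of target probe sets, 6 of 28 groups of array measures, 3 of 72 groups of list means and 65 of 688 groups of named genes. In these, Bcl6b knockdown replicate 1 accounted for 4, 6, 3 and 36.

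Bcl6b knockdown replicate 1 stood apart in its mean correlation with the other arrays (0.964), in the 3' minus 5' signal of Gapdh (1.03) and Actb (3.08), in the hybridisation controls BioB (733) and BioC (1790) and in the Lys control (112). It also did so in 3 Etv5 probe sets (62.0, 1660 and 51.1), a Pou3f1 probe set (424), 36 of 172 named genes and the list means of S phase (-0.325), unfolded protein (0.159) and glycolysis genes (0.247). A transcript-wide change in those cells was argued against as the main source of the deviations. In the brightest and next brightest probe set of 5324 genes they correlated at only 0.16 ± 0.0136 (SE). On the other arrays this was 0.0519 to 0.2775, with smaller deviations (SD at most 0.1519, against 0.6275). A change of expression beside another cause cannot be excluded by this. The sample of an Etv5 knockdown under a wrong label was argued against, because over 8 genes that fell in Etv5 knockdown the array's median difference from control was 0.51, and the Etv5 knockdown median -1.13. RNA degradation or poor labelling of that array may account for it, since the smaller of its 3' excesses over every other array was 1.48. No biological explanation other than these was tested.

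The genes higher in all 3 knockdowns numbered 68. Chance alone was argued against, with 0 of 100 simulated draws without any knockdown effect giving as many. Such draws hold no separate effects of the knockdowns. Sharing through the control arrays in the presence of such effects was therefore not tested by them. A deviating control array was argued against: genes chosen anew with 3 control arrays (44 to 51) rose by a median of at least 0.443 over the control array not used in the choice. Their median rise over the 3 arrays used was 0.483 to 0.531. An effect of the control siRNA, or of how the control arrays were made, could give equal rises in each knockdown, and the median spread between the 3 rises was 1.44 standard errors, where simulated equal rises gave 1.14. It cannot be told apart from an effect that the 3 knockdowns share, because the design holds 1 control siRNA.

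Interferon-stimulated genes differed between knockdowns in direct tests, by a list mean of 1.02 between Bcl6b and Pou3f1 knockdown and 0.837 between Etv5 and Pou3f1 knockdown. More leukocytes in Bcl6b knockdown were argued against, because the 9 macrophage markers had a median difference of -0.0118 ± 0.0508 (SE), against 1.03 for the interferon list. Some of these lie near the floor of the signal, and the 6 that read 67.9 to 318 in control had a median of 0.0705 ± 0.0705 (SE). The scaling of the arrays was argued against, because the mean difference was still 0.965 or more under median centring and quantile normalization. siRNA duplexes that evoke interferon-stimulated genes to different degrees may account for the pattern, as may loss of the targets: the highest Pou3f1 knockdown array had a list mean of -0.495, below the lowest of the others at -0.134. These cannot be told apart, because each target was lowered with its own siRNA. Whether the interferon difference arose in the germ cells or in other cells of the cultures was not tested.

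Etv5 knockdown replicate 3 had the highest Etv5 of its group on all 3 probe sets, at 1680 against 898 to 912, 420 against 171 to 205 and 252 against 101 to 130. The last of these did not meet Dixon's criterion. Bcl6b was also highest there, at 899 against 608 to 620. Pou3f1 knockdown replicate 3 read 156 on the dimmer Pou3f1 probe set, against 105 to 106 on the others of its group, and 519 on the brighter one, against 354 to 393, which did not meet the criterion.

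Of the 35 ways to split the 8 arrays of each comparison only 1, the real one, gave as many called genes, which argues against chance. A share of 1 in 35 is the lowest that this test can give. In the other splits the real difference widens the spread, so low counts there were likely beforehand. The test cannot tell an effect of the siRNA from another difference between the cultures or preparations of the groups. The real counts were 233, 358 and 251 for Etv5, Bcl6b and Pou3f1 knockdown against control, and 161 and 243 for Etv5 and Bcl6b knockdown against Pou3f1 knockdown, and the highest other split gave 0 in each. Etv5 against Bcl6b knockdown gave 166, and the highest other split 6.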

How the results depend on the processing

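The settings without Bcl6b knockdown replicate 1 were chosen only after the result was seen for Etv5 and Pou3f1 knockdown against control, for the difference between these, for the calls they share and for list tests. Counts are given in the order Etv5, Bcl6b and Pou3f1 knockdown against control, then Etv5 against Bcl6b, Etv5 against Pou3f1 and Bcl6b against Pou3f1 knockdown. Without that array, which widened the residual spread, they were 1061, 1220, 1268, 502, 709 and 570, the highest values with any array left out. The lowest were 128 (without control replicate 3), 191 (control replicate 2), 129 (control replicate 3), 74 (Etv5 knockdown replicate 1), 85 (Etv5 knockdown replicate 4) and 166 (Pou3f1 knockdown replicate 2). Leaving out any control array gave at most 144 genes for Etv5 knockdown and 196 for Bcl6b knockdown, and control replicate 1, 2 or 3 at most 145 for Pou3f1 knockdown. Without Etv5 knockdown replicate 1, 2 or 4 there were 132, 138 and 136 for Etv5 knockdown and 74, 110 and 83 against Bcl6b knockdown, and without replicate 1 there were 99 against Pou3f1 knockdown. Without Bcl6b knockdown replicate 2 there were 230 for Bcl6b knockdown. Without Pou3f1 knockdown replicate 2, 3 or 4 there were 151, 144 and 161 for Pou3f1 knockdown, and without replicate 2 or 3 there were 105 and 99 for Etv5 against Pou3f1 knockdown. Calls shared by Etv5 and Bcl6b knockdown ranged from 63 (without control replicate 2 or 3) to 421, by Etv5 and Pou3f1 knockdown from 56 (control replicate 3) to 466 and by Bcl6b and Pou3f1 knockdown from 57 (control replicate 3) to 496.

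Array weights, whose iteration stopped before it converged, gave 1662, 2082, 1744, 1032, 954 and 908 genes, and 720, 653 and 790 shared calls. Fitting only the groups compared gave 996, 62, 1140, 2, 325 and 74. Median centring gave 154 genes for Etv5 knockdown, 743 for Bcl6b knockdown, 259 between these and 73 shared calls. Array medians were 16.0 to 17.1 in Bcl6b knockdown and 15.6 to 16.3 in control. Centring therefore lowered Bcl6b knockdown values on average against control, by medians that lie near the floor of the signal. Whether this accounts for all the changed counts was not tested. Counting all probe sets gave 908 for Bcl6b knockdown against control and 1096 for Bcl6b against Pou3f1 knockdown, with 22836 probe sets tested. Under the mean over probe sets Ret differed by -0.0590 in Bcl6b knockdown and Ccng1 by -0.0565 between Bcl6b and Pou3f1 knockdown, opposite to their brightest probe sets. At the preset correlation the interferon list kept its call in Pou3f1 knockdown and in both differences from it under all alternatives, and with an estimated correlation 28 of all 31 list calls were lost. The G2 and M phase list lost its call in Etv5 knockdown without Etv5 knockdown replicate 1 (adjusted p 0.0704) or 4 (0.254) or control replicate 3 (0.0745), and in Bcl6b knockdown without control replicate 2 (0.0578) or 3 (0.0842) or Bcl6b knockdown replicate 1 (0.492). Between Bcl6b and Pou3f1 knockdown it lost its call without Bcl6b knockdown replicate 1 (0.256) or Pou3f1 knockdown replicate 3 (0.272). Germ cell identity genes lost theirs in Etv5 knockdown without Etv5 knockdown replicate 3 (0.0804) or control replicate 4 (0.112). Fibroblast markers lost theirs between Etv5 and Bcl6b knockdown without Etv5 knockdown replicate 4 (0.0593) and under the mean over probe sets (0.170). Without a filter on dim genes fibroblast markers (0.125) and germ cell identity genes (0.228) lost theirs in Etv5 knockdown, as did G2 and M phase genes between Bcl6b and Pou3f1 knockdown (0.0971). Under the mean over probe sets glycolysis (0.0629) and G2 and M phase genes (0.335) lost theirs in Bcl6b knockdown, as did the latter against Pou3f1 knockdown (0.184). With array weights G2 and M phase genes lost theirs in Bcl6b knockdown against control (0.376) and against Pou3f1 knockdown (0.117), and cholesterol synthesis genes in the latter (0.0987). Quantile normalization ended the call of G2 and M phase genes in Bcl6b knockdown (0.0681). Between Etv5 and Pou3f1 knockdown the FGF, G2 and M phase, cholesterol and glycolysis lists each lost their call under several settings, at adjusted p of up to 0.317, 0.399, 0.303 and 0.148. Dim probe sets lie near the floor of the signal, which limits what can be seen in them.

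No clear pairing by replicate number was seen: deviations of same-numbered arrays correlated between -0.263 and 0.202 (median 0.0623), with 5 of 24 pairs over 0.1. The best partner had the same number in 10 of 24, more than random picks would give on average. A weak effect shared by same-numbered arrays is therefore not excluded. With the replicate block the counts were 177, 277, 195, 136, 131 and 208.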

Other observations

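The tests without Bcl6b knockdown replicate 1 were chosen only after the result was seen. Without that array further genes passed in Etv5 knockdown against control. The self-renewal gene Id4 fell (log2 difference -0.34, adjusted p 0.00266), as did the MAPK feedback inhibitors Spry4 (-0.38) and Dusp6 (-0.40). Klf4 rose by 0.32, Zbtb16 by 0.25 and the receptor gene Kit of differentiating spermatogonia by 0.19. The glycolytic genes Aldoa, Tpi1 and Pgk1 rose by 0.18, 0.17 and 0.14, and the glucose transporter gene Slc2a3 fell (-0.36). In Bcl6b knockdown the cholesterol transport gene Star fell (-0.21), and the interferon-stimulated genes Mx1, Cxcl10 and Ifit3 rose by 0.89, 0.68 and 0.43.

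Fibroblast and feeder markers also passed without that array. In Etv5 knockdown Postn rose by 0.19, Pdgfra by 0.12, Pdgfrb by 0.24 and Ccn2 by 0.27, and the list was higher at an adjusted p of 0.00615 (adjusted p = 0.212 with an estimated correlation). In Bcl6b knockdown Pdgfrb rose by 0.30, and Lox (-0.14) and Thbs1 (-0.26) fell. In Pou3f1 knockdown Col1a1 (-0.23), Thbs1 (-0.22), Sparc (-0.15) and Fn1 (-0.12) fell and Postn rose by 0.15, and the list did not pass (adjusted p 0.813).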
